A study of Danio rerio with 8 samples.

How the data were processed

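RNA was measured in GFP-positive cells sorted from zebrafish larvae that carry GFP under the control of the pdgfrb promoter, through the Gal4ff and UAS expression system. The transgene marks fibroblast-like cells of the myosepta, the connective tissue sheets between muscle segments, and cells around blood vessels. The labels give 8 libraries, 4 from larvae with a mechanical lesion of the spinal cord 1 day before collection and 4 from unlesioned larvae, all 4 days after fertilization. The tissue was dissociated with trypsin, the cells were sorted by flow cytometry, and full-length cDNA was made by the SMART-seq2 method and sequenced on a NextSeq500. The labels do not say how many larvae went into a library, or whether the libraries come from separate clutches or animals. The p-values therefore measure the spread between these libraries, which may be technical.

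The deposited table holds raw read counts per gene, with no normalization by the authors. Per the labels, reads were demultiplexed with bcl2fastq 2.19.1, aligned with GSNAP 2018-07-04 to the zebrafish genome build GRCz11 and counted with featureCounts 1.6.2. The file header names featureCounts 1.6.3, with the Ensembl 92 annotation, a minimum mapping quality of 1 and strand setting 0, that is, without regard to strand. Reads from an overlapping or antisense gene can therefore not be told from those of the gene itself. Of the 89 genes named by the rule given further on, 10 share exon bases with another gene, and 5 of these share over 10% of them. The 5 are fkbp9 (21.2%), sec13 (11.1%), fosab (26.8%), pnp4a (11.1%) and paics (18.7%). The table has 31901 genes and 92 entries for synthetic spike-in RNAs, which were left out of all fits. The libraries were counted one by one, and none was pooled.

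The total counts ranged from 19552807 to 25358885 per library. The reads carry no molecular identifiers, so the counts are not independent molecules, and a limit from a count of 0 (3 counts) covers counting error only. Precision was set by the spread between libraries more than by depth, since the common dispersion of 0.561 corresponds to a biological coefficient of variation of 74.9%.

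The table gives gene identifiers only. Symbols were found for 29178 identifiers, of which 16585 had a zebrafish symbol in the reference table. Another 10986 carried a symbol in capitals and were assigned to a zebrafish gene by comparing 15 neighbouring genes on each side, with at least 2 shared neighbours required, and 1607 kept the symbol in capitals. For 2723 identifiers no symbol was found. The matching was checked on 5139 paralogs of known symbol, of which 3375 were returned with their own symbol, 3 with another and 1761 were not resolved.

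Lesioned was compared with unlesioned in edgeR 4.0.16 under R 4.3.3, with TMM factors, the filterByExpr filter, a robust quasi-likelihood fit and a two-sided quasi-likelihood F-test. The filter left 15759 genes. Values of p were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are log2 of lesioned over unlesioned with the standard error of the fit, and levels are CPM, that is, counts scaled to the library total adjusted by its TMM factor, with the SD of 4 libraries. The groups of a gene are said not to overlap where each lesioned library lies on one side of each unlesioned library.

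Before the data were examined, 27 gene lists were fixed, of which 10 hold markers of other cell types. Each list was tested against the other genes with camera of limma 3.58.1, on log CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists. The same test with an estimated correlation was run alongside, as was fry, which asks whether the genes of a list move on balance one way, or, in its mixed form, in either direction. Neither form of fry compares a list with other genes. Shares of counts and other measures per library were compared by an exact two-sided permutation test over 70 arrangements, whose smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over 17 measures.

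The genes named in the text follow a rule also fixed beforehand. It takes pdgfrb, up to 10 called genes per direction with the largest fold change, a mean of at least 10 CPM and groups that do not overlap, and from each list the 3 members with the lowest adjusted p (2 for markers of other cell types) and the most abundant one. A gene named outside this rule is said to have been chosen after its values were seen.

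The replicate numbers were checked for pairing by correlating, across genes, the deviations of the libraries from their group means. The 4 pairs with the same number gave 0.192, 0.182, 0.232 and 0.154, each over the limit of 0.1 set beforehand, so the numbers pair the samples by that rule. The pairing comes from the data and not from the labels, and lesioned 1 correlated slightly better with unlesioned 2 (0.199). Libraries 1 and 2 of both groups also differed from libraries 3 and 4 of both groups in mitochondrial share and spike-in counts. The labels name no batch, so this division of the samples was found in the data, and values within each part stand beside the pooled ones for the called genes and lists, the number of genes detected and the skeletal muscle list. A chi-square comparison of counts between libraries of a group (from 51.1 to 287 per degree of freedom) gave no sign of a library deposited more than once. The lowest values were those between libraries 1 and 2 (51.1 unlesioned, 55.1 lesioned). Libraries 3 and 4 differed far more from each other (246 and 244), so they are not a uniform part.

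The alternatives fixed beforehand were other size factors, DESeq2 1.42.0, limma voom with and without sample quality weights, no filter on low counts and a stricter one (5 CPM in 4 libraries), glmTreat against a 1.5-fold change, a replicate block, shares without mitochondrial genes, and each library left out in turn. A batch term for libraries 1 and 2 against 3 and 4, and fits of each part alone, were added after seeing the data. The tests were tried on simulated data with 50 changed genes at each of 4 fold sizes. The edgeR test called 2% of genes with a 2-fold change, 26% at 4-fold, 58% at 8-fold and 74% at 16-fold, and 5 of its 85 calls (5.88%) were false. DESeq2 made 167 calls on the same kind of data, of which 65 (38.9%) were false. Camera found the list raised in the simulation and called 0 of the other 26. The simulated genes varied independently of each other, so false calls on lists of correlated genes could not appear there. The counts were drawn with the dispersions that edgeR had estimated, which may favour edgeR over DESeq2. They held no difference between libraries 1 and 2 and libraries 3 and 4.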

Results

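The data are RNA-seq counts of sorted pdgfrb-reporter cells from larval zebrafish, a species that regrows spinal axons after injury. Total counts were 21356630, 19552807, 25358885 and 22101332 in unlesioned 1 to 4, and 21589538, 22183392, 23754652 and 20811678 in lesioned 1 to 4. The design holds a single comparison, which asks how the transcriptome of these cells differs 1 day after a spinal lesion.

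Genes with at least 1 count numbered 19674 ± 327 in the unlesioned and 20975 ± 507 in the lesioned libraries (SD, n = 4 each). All 4 lesioned libraries lay above all unlesioned ones, the smallest p of an exact two-sided permutation test (0.0286), with a Benjamini-Hochberg adjusted p of 0.243 over 17 measures. The difference was 1789 genes in libraries 1 and 2 and 814 in libraries 3 and 4. The mitochondrial share of counts was 12.1 ± 3.77% in the unlesioned and 12.8 ± 3.46% in the lesioned group (exact permutation p = 0.686). That test leaves the pairing by number out. The share was 8.91%, 8.98%, 16.5% and 13.8% in unlesioned 1 to 4, and 9.54%, 10.2%, 16.8% and 14.5% in lesioned 1 to 4, so slightly higher in lesioned at each number. The mitochondrial share averaged 9.41% in libraries 1 and 2 and 15.4% in libraries 3 and 4 of both groups together, and the 10 most abundant genes took 15.4% and 22.8%. The first 4 principal components of log CPM held 26.7%, 18.3%, 17.5% and 14.0% of the variance.

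**Figure D1:**
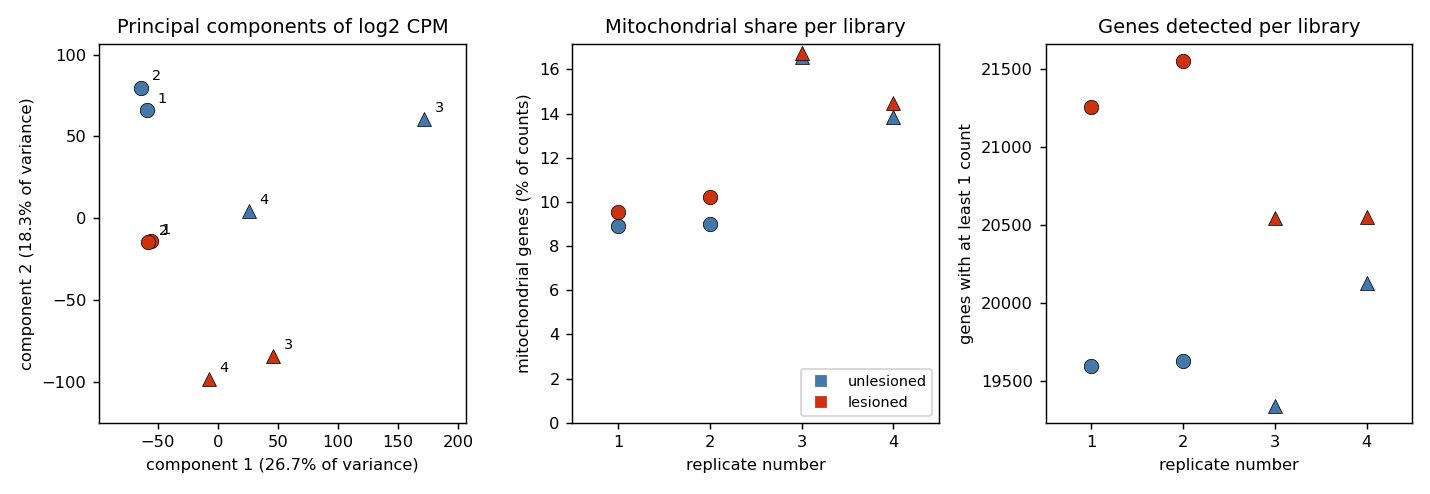
Each point is 1 of 8 libraries, by group and replicate number. The panels show the first 2 principal components of log CPM (26.7% and 18.3% of variance), the mitochondrial share of counts in percent, and the number of genes detected. Libraries 3 and 4 of both groups have mitochondrial shares from 13.8% to 16.8%, libraries 1 and 2 from 8.91% to 10.2%, and the lesioned libraries detect more genes than the unlesioned ones.

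After the lesion, c4b, efemp2a and adamtsl7 rose in the sorted cells. The complement component gene c4b went from 0.192 ± 0.136 to 193 ± 114 CPM (SD, n = 4 each), a log2 fold change of 9.92 ± 0.91 (SE, adjusted p = 0.00316 in edgeR with Benjamini-Hochberg adjustment). The gene efemp2a encodes an extracellular matrix protein of the fibulin family. It went from 39.3 ± 9.54 to 438 ± 102 CPM, a log2 fold change of 3.48 ± 0.27 (adjusted p = 0.00187 in edgeR). The gene adamtsl7, of the ADAMTS-like family of secreted matrix proteins, went from 26.1 ± 9.76 to 325 ± 78.0 CPM, a log2 fold change of 3.64 ± 0.33 (adjusted p = 0.00316 in edgeR). Each of the 3 genes was higher in 4 of 4 lesioned libraries than in any unlesioned library.

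On GRCz11, c4b (ENSDARG00000038424) lies on the minus strand of chromosome 16 from 16665203 to 16701718, efemp2a (ENSDARG00000094324) on chromosome 14 from 30669662 to 30704075, and adamtsl7 (ENSDARG00000055439) on chromosome 1 from 21576674 to 21599219, also on the minus strand. None of the 3 shares exon bases with another annotated gene. The log2 fold changes in libraries 1 and 2 and in libraries 3 and 4 were 11.15 and 9.05 for c4b, 3.22 and 3.81 for efemp2a, and 3.96 and 3.35 for adamtsl7. Counts of c4b were 2, 2, 8 and 4 in the unlesioned and 5547, 5691, 6110 and 574 in the lesioned libraries. With the replicate number as a block, adamtsl7 lost its call (adjusted p = 0.0658 in edgeR), and over all settings tried its adjusted p ranged from 1.1e-21 with DESeq2 to 0.892 in libraries 3 and 4 alone. In limma voom c4b lost its call (adjusted p = 0.272), and its adjusted p ranged from 1.4e-33 with DESeq2 to 0.892 in libraries 3 and 4 alone. In libraries 1 and 2 alone efemp2a had an adjusted p of 0.0505, with a range from 8.5e-30 with DESeq2 to 0.892 in libraries 3 and 4 alone.

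Of 15759 genes tested in edgeR, 3 rose and 0 fell. At an unadjusted p under 0.05, 957 genes were higher and 864 lower, against 788 in all by chance, and with library size as the only scaling 1316 were higher and 524 lower. DESeq2 called 406 higher and 272 lower, and limma voom 3 and 0. The groups did not overlap for 839 genes that were higher and 616 that were lower, 9.23% of those tested, where chance gives 2.86%. Without unlesioned 3, 7 genes were called higher and 1 lower. With that scaling the median log2 fold change of all genes moved from -0.04 to 0.12, and the changes given here are relative to TMM scaling. The reporter's own gene pdgfrb (ENSDARG00000100897, chromosome 14 from 3186485 to 3268155), a receptor for platelet-derived growth factor, had 213 ± 27.4 CPM in the unlesioned and 195 ± 68.5 CPM in the lesioned group. Its log2 fold change was -0.13 ± 0.27 (SE, adjusted p = 0.924 in edgeR).

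**Figure D2:**
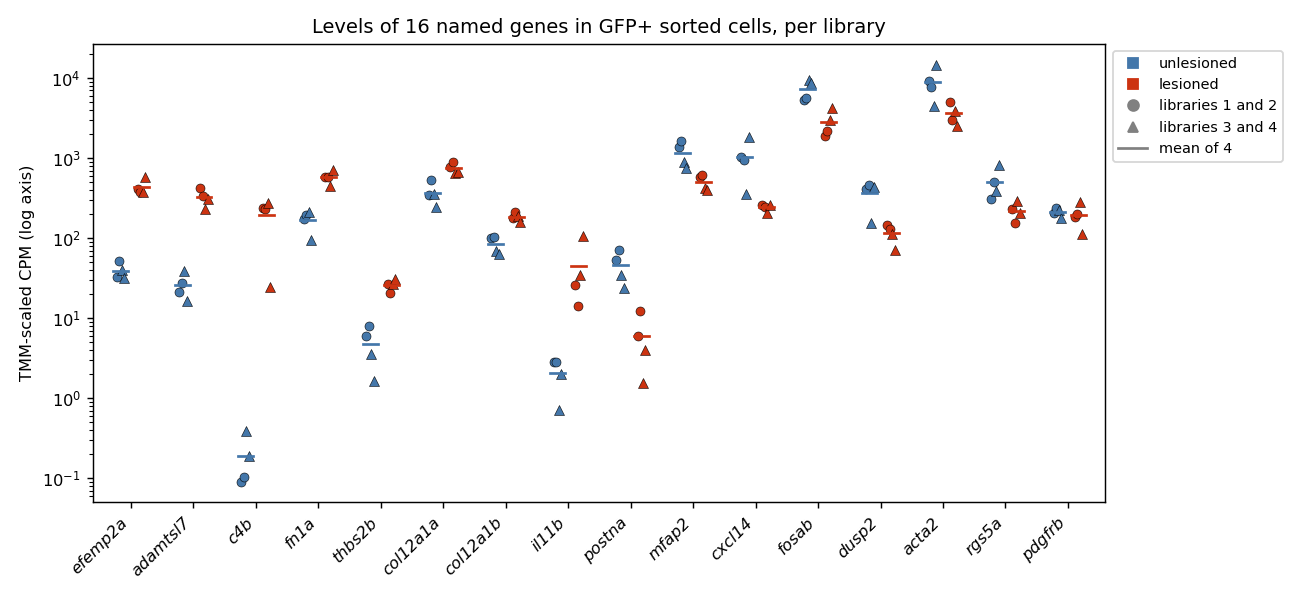
Level of 16 named genes in each library, as TMM-scaled CPM on a log axis, with unlesioned libraries in blue and lesioned ones in red. Circles are libraries 1 and 2, triangles libraries 3 and 4, and bars the mean of 4 libraries. The 3 called genes c4b, efemp2a and adamtsl7 have lesioned libraries above all unlesioned ones, and pdgfrb overlaps between the groups (213 and 195 CPM).

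Of the genes on the matrix lists, efemp2a alone passed over all genes in the main fit, and camera called none of these lists. In the list of matricellular and provisional matrix glycoproteins, proteins of early wound matrix, 0 of 28 tested members passed over all genes, and 2 were higher and 1 lower when adjusted over the list alone. They were fn1a, a fibronectin (170 ± 51.9 and 581 ± 108 CPM in the unlesioned and lesioned groups, log2 fold change 1.77 ± 0.28), thbs2b, a thrombospondin (4.80 and 26.2 CPM, 2.45 ± 0.48), and postna, a periostin (46.2 and 5.98 CPM, -2.95 ± 0.61, and -3.57 without lesioned 2). In other settings fn1a passed over all genes with DESeq2 (adjusted p = 1.9e-05), with sample quality weights in limma voom (0.0162) and with no filter in edgeR (0.0451). With the batch term postna passed in edgeR (adjusted p = 0.0475). With the replicate block neither did (0.127 for fn1a and 0.101 for postna in edgeR). The median log2 fold change of the matricellular list was -0.12 and its mean 0.03, and camera gave Down with an adjusted p of 0.842. Its most abundant member tgfbi had 5371 and 2468 CPM. Among interstitial collagens, 0 of 27 passed over all genes, and 2 were higher and 1 lower when adjusted over the list alone. These were col12a1b (84.0 and 185 CPM), col12a1a (370 and 746 CPM), both chains of a fibril-associated collagen, and col27a1b (14.8 and 5.22 CPM). The most abundant collagen gene, col1a1a, had 5401 ± 2123 and 6568 ± 2321 CPM, and the list had a median of 0.09 (camera adjusted p = 0.919). Both lists hold genes for which this study is known, so their direction is not independent evidence.

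Chosen after its values were seen, tncb, a tenascin gene, had 370 ± 175 CPM in the unlesioned and 752 ± 67.1 CPM in the lesioned group, and its log2 fold change of 1.03 had an adjusted p of 0.288 in edgeR. Also chosen after its values were seen, cthrc1a had 138 ± 149 and 479 ± 71.8 CPM, a log2 fold change of 1.80 with an adjusted p of 0.354 in edgeR. All 4 lesioned libraries lay above all unlesioned ones for both genes.

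In the microfibril and elastic fibre list 1 of 13 members rose over all genes, efemp2a, and 1 was higher and 2 lower when adjusted over the list alone. The lower members were mfap2, a microfibril component (1168 ± 414 and 507 ± 107 CPM), and emilin1b (72.6 and 39.6 CPM). Over all genes mfap2 passed with the batch term (adjusted p = 0.0475 in edgeR), but not with the replicate block (0.101). The list had a median of -0.32 (camera adjusted p = 0.411), and the mixed form of fry gave an adjusted p of 4.3e-06. That form gave 6.4e-05 for the matricellular list and passed for 15 of the 27 lists, while the one-way form passed for 1. For proteases and their inhibitors 0 of 30 members passed over all genes, and 1 was higher when adjusted over the list alone, adam9a (7.85 and 22.0 CPM). The median of that list was 0.08 (camera adjusted p = 0.563). Its member timp2b, a protease inhibitor, had 177 ± 193 and 810 ± 238 CPM (adjusted p = 0.225 in edgeR). Without unlesioned 3, which held 465 CPM, its adjusted p was 0.0184, and cxcl14 had the same adjusted p there.

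In 3 further matrix lists 0 members passed, over all genes or adjusted over the list alone. The basement membrane list (28 tested) had a median of -0.23 (camera adjusted p = 0.202), with fras1 at 70.4 and 33.1 CPM and lamb2, a laminin chain, at 10.3 and 26.4 CPM. Small leucine-rich proteoglycans (15 tested) had a median of -0.09, a mean of 0.10 and a camera direction of Down (adjusted p = 0.523), with lum, a lumican, at 984 and 410 CPM. The list of collagen folding and cross-linking (36 tested) had a median of -0.09, a mean of 0.00 and a camera direction of Up (adjusted p = 0.523), with fkbp9 at 245 and 455 CPM and p4hb at 22.6 and 51.6 CPM. With library size alone as scaling, the medians of the matricellular, proteoglycan and collagen folding lists turned positive (0.04, 0.07 and 0.09).

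Immediate early and heat shock genes, which respond within minutes to stimuli that include tissue dissociation, fell as a list. Of 54 tested members 50 had a negative log2 fold change, the median was -0.76, and camera gave an adjusted p of 3.9e-08. With an estimated correlation the adjusted p was 0.305. None of the members passed over all genes, and 3 were lower when adjusted over the list alone. They were fosab, a Fos transcription factor (7319 ± 2077 and 2823 ± 1053 CPM), dusp2, a phosphatase of MAP kinases (367 and 115 CPM), and egr1 (1029 ± 84.3 and 536 ± 134 CPM). The chaperone hspa8 had 9450 and 9699 CPM. The median of the list was -0.75 in libraries 1 and 2 and -0.58 in libraries 3 and 4.

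Genes of protein folding and export in the endoplasmic reticulum rose as a list. Of 51 tested members 45 had a positive log2 fold change, with a median of 0.46 (camera adjusted p = 7.3e-07; adjusted p = 0.683 with an estimated correlation). None passed over all genes, and 10 were higher and 1 lower when adjusted over the list alone. The higher ones included sec13 and sec23a, parts of the COPII vesicle coat (39.0 and 102 CPM, and 27.4 and 76.6 CPM), and copa of the COPI coat (90.6 and 179 CPM). The lower one, atf4b, named after its values were seen, encodes a transcription factor of the stress response (3091 and 1847 CPM). The chaperone hspa5 had 3116 ± 2079 and 3481 ± 2035 CPM. The list median was 0.48 in libraries 1 and 2 and 0.50 in libraries 3 and 4.

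Cell cycle genes rose as a list with a median of 0.33 and 32 of 47 members positive (camera adjusted p = 0.0307; adjusted p = 0.819 with an estimated correlation). None passed over all genes or adjusted over the list alone. Examples are uhrf1 (20.5 and 56.6 CPM), fen1 (61.2 and 134 CPM) and pcna, the sliding clamp of DNA replication (326 and 660 CPM). The median was 0.15 in libraries 1 and 2 (camera adjusted p = 0.846) and 0.65 in libraries 3 and 4 (0.00805). The call was lost without unlesioned 2 (camera adjusted p = 0.0657), unlesioned 3 (0.0724), unlesioned 4 (0.935), lesioned 1 (0.231) or lesioned 4 (0.221). Genes of glycolysis and hypoxia (40 tested) had a median of 0.03, with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.523), and hk2, a hexokinase, had 24.5 and 59.2 CPM.

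Actin and contractile genes fell as a list, with 21 of 30 members negative and a median of -0.48 (camera adjusted p = 0.00436; adjusted p = 0.683 with an estimated correlation). None passed over all genes, and 7 were lower when adjusted over the list alone, among them acta2, the smooth muscle actin (9028 ± 4234 and 3623 ± 1131 CPM), and the tropomyosins tpm1 (4412 and 1850 CPM) and tpm2 (2310 and 961 CPM). The cytoplasmic actin gene actb2 had 7430 and 7441 CPM. The list median was -0.26 in libraries 1 and 2 (camera adjusted p = 0.0978) and -0.56 in libraries 3 and 4 (0.0155).

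Markers of mural cells, which surround blood vessels, fell as a list, with 22 of 30 members negative and a median of -0.36 (camera adjusted p = 0.0244; adjusted p = 0.683 with an estimated correlation). None passed over all genes or adjusted over the list alone. The signalling regulator rgs5a had 503 ± 222 and 221 ± 54.6 CPM, the smooth muscle myosin myh11a 1867 and 953 CPM, and cd248b 61.9 and 174 CPM. These genes took 0.422 ± 0.164% of counts in the unlesioned and 0.283 ± 0.0435% in the lesioned libraries (exact permutation p = 0.114). Unlesioned 4 carried much of this difference with 0.657%, against 0.384%, 0.374% and 0.275% in unlesioned 1 to 3. The list median was -0.31 in libraries 1 and 2 (camera adjusted p = 0.0540) and -0.47 in libraries 3 and 4 (0.175). The call was lost without unlesioned 2 (camera adjusted p = 0.169), unlesioned 3 (0.0823), unlesioned 4 (0.0646) or lesioned 4 (0.284).

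Sclerotome, tenocyte and myoseptal fibroblast markers also fell as a list, with 22 of 30 members negative and a median of -0.41 (camera adjusted p = 0.0307; adjusted p = 0.707 with an estimated correlation). None passed over all genes, and 4 were lower when adjusted over the list alone. Among them were egr1 (1029 and 536 CPM), the tendon gene tnmd (642 ± 404 and 187 ± 69.8 CPM) and fgfrl1a (170 and 94.9 CPM). The markers of this list took 0.50 ± 0.0785% of counts in the unlesioned and 0.376 ± 0.0478% in the lesioned libraries (exact permutation p = 0.0571). Since egr1 is also in the immediate early list that fell, the fall of the 2 lists is partly the same one. The median was -0.48 in libraries 1 and 2 (camera adjusted p = 0.0293) and -0.22 in libraries 3 and 4 (0.434). The call was lost without unlesioned 1 (camera adjusted p = 0.0871), unlesioned 2 (0.195), unlesioned 3 (0.197) or lesioned 4 (0.221).

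Signalling genes did not pass over all genes. Of 43 inflammatory signalling genes, 1 was higher and 2 were lower when adjusted over the list alone. They were the cytokine il11b (2.1 ± 0.994 and 45.5 ± 41.9 CPM, log2 fold change 4.43 ± 0.72), the chemokine cxcl14 (1040 ± 601 and 243 ± 26 CPM, -2.1 ± 0.41) and ptgs2a, a cyclooxygenase of prostaglandin synthesis (786 and 335 CPM). The log2 fold change of il11b was 2.83 in libraries 1 and 2, 5.76 in libraries 3 and 4 and 3.57 without lesioned 4, which held 107 CPM. The list had a median of -0.52 and a camera adjusted p of 0.0863, and with the replicate number as a block the list was called (camera adjusted p = 0.0417). It was also called without unlesioned 1 (0.0175) or lesioned 3 (0.0110), and over all settings tried its adjusted p lay between the last value and 0.707 with an estimated correlation.

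Of 47 components of the TGF-beta, BMP and PDGF pathways 0 passed over all genes, and 0 were higher and 2 lower when adjusted over the list alone, with a list median of -0.24 (camera adjusted p = 0.0863). They were fsta, a follistatin that binds activins (152 and 47.6 CPM), and bmp4, a bone morphogenetic protein (276 and 142 CPM). The list was called without unlesioned 4 (camera adjusted p = 0.0415) and with the stricter filter on low counts (0.0384). Wnt pathway feedback targets (22 tested) had 0 members passing, over all genes or adjusted over the list alone, and a median of -0.36 (camera adjusted p = 0.518). Their member fzd7b, a Wnt receptor, had 231 ± 28.9 and 138 ± 14.1 CPM.

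**Figure D3:**
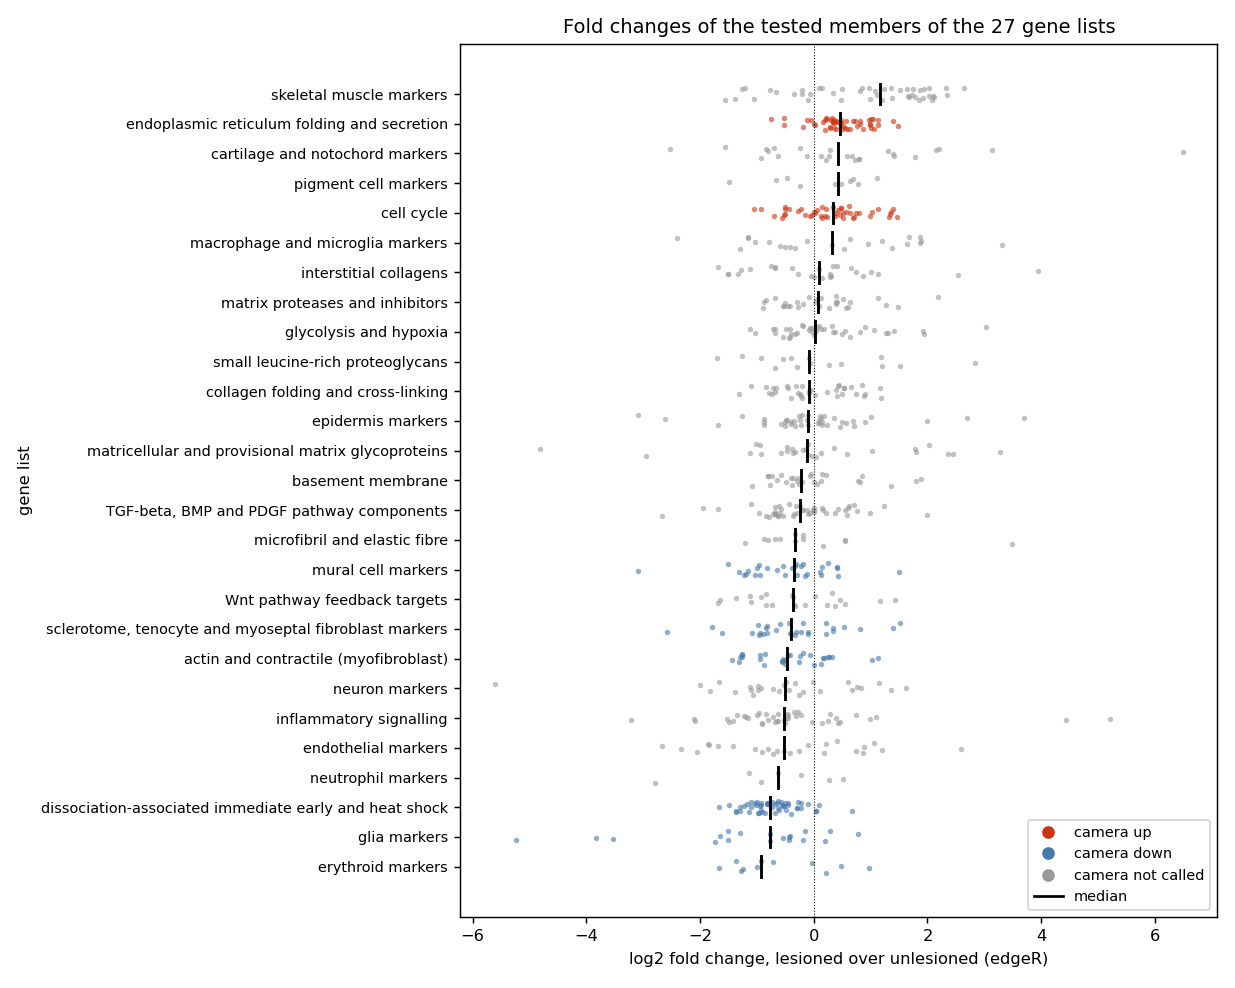
Log2 fold change (lesioned over unlesioned) of each tested member of the 27 gene lists, with 1 point per gene and a line at the list median. Lists that camera with a preset correlation called are red (up) or blue (down), and the others grey. The immediate early and heat shock list has a median of -0.76 and the endoplasmic reticulum list of 0.46. The skeletal muscle list has a median of 1.16 and was not called.

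Markers of 10 other cell types were measured in the same libraries. Of these lists, glia and erythroid markers fell. Glial genes had a median of -0.76 with 16 of 19 negative (camera adjusted p = 0.0244, or 0.305 with an estimated correlation), with fabp7a at 15.9 ± 26 and 1.36 ± 1.28 CPM. Most of the unlesioned level of fabp7a came from unlesioned 2 (54.8 CPM, the other unlesioned libraries at most 5.49). Erythroid genes had a median of -0.92 with 8 of 11 negative (camera adjusted p = 0.0307, or 0.305 with an estimated correlation), with rhag at 395 ± 161 and 198 ± 36.0 CPM. Other members were far lower, such as sptb (44.2 and 23.4 CPM), hemgn (5.17 and 3.15 CPM) and the globin gene hbae1.1 (3.95 and 1.62 CPM). The level of the list rests mostly on rhag, so its fall does not show fewer red blood cells. Erythroid markers were also the list that passed the one-way form of fry (adjusted p = 0.00574). The glia median was -0.68 in libraries 1 and 2 (camera adjusted p = 0.101) and -0.59 in libraries 3 and 4 (0.649), and the erythroid median -1.06 (0.0518) and -0.76 (0.264). No member of the glia and erythroid lists passed over all genes or adjusted over the list alone. The glia call was lost without unlesioned 2 (camera adjusted p = 0.197), unlesioned 3 (0.149), lesioned 2 (0.0863), lesioned 3 (0.0589) or lesioned 4 (0.0686). The erythroid call was lost without unlesioned 1 (0.0588), unlesioned 2 (0.109), unlesioned 3 (0.149), lesioned 1 (0.0822), lesioned 2 (0.0769), lesioned 3 (0.110) or lesioned 4 (0.0529). With no filter on low counts both calls were lost (0.340 for glia and 0.15 for erythroid markers).

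Skeletal muscle markers (46 tested) had a median of 1.16 (camera adjusted p = 0.523), but the parts of the samples went opposite ways. In libraries 1 and 2 the median was -1.0 (camera Down, adjusted p = 0.000608), and in libraries 3 and 4 it was 2.33 (camera Up, adjusted p = 1.6e-07). Without lesioned 1 the list was called (0.0368). The most abundant member, tpm2, is also in the contractile list (2310 and 961 CPM), actc1a had 565 ± 254 and 192 ± 121 CPM, and muscle genes took 0.566 ± 0.251% and 0.492 ± 0.237% of counts (exact permutation p = 0.686). Macrophage and microglia markers (23 tested) had a median of 0.32 (camera adjusted p = 0.202), with apoeb at 112 ± 148 and 348 ± 406 CPM. That list was called without unlesioned 4 (0.00840) or lesioned 1 (0.00596).

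Endothelial markers (25 tested) had a median of -0.52 (camera adjusted p = 0.185), and 1 was lower when adjusted over the list alone, egfl7, a secreted vessel protein (20.8 ± 4.48 and 5.02 ± 1.74 CPM). Neuron markers (28 tested) had a median of -0.51 (camera adjusted p = 0.298), with rtn1a at 55.8 and 28.4 CPM. Neutrophil markers (7 tested) had a median of -0.63 (camera adjusted p = 0.523), with nccrp1 at 72.9 and 47.1 CPM. Epidermis markers (43 tested) had a median of -0.10, or 0.06 with library size alone (camera adjusted p = 0.768), and 1 was lower when adjusted over the list alone, s100v2 (232 and 126 CPM). Cartilage and notochord markers (26 tested) had a median of 0.43 (camera adjusted p = 0.523), with matn4, a matrilin, at 1086 and 621 CPM. Pigment cell markers (10 tested) had a median of 0.43 (camera adjusted p = 0.668), with pnp4a at 192 and 68.5 CPM. No gene of these lists passed over all genes. None of the 17 measures of library composition had an adjusted p under 0.05 by the exact permutation test. That test could hardly give one, since the number of genes detected, at its smallest p of 0.0286, had an adjusted p of 0.243. The result therefore does not show that composition was alike in the groups.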

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

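The tests of parts of the samples, of handling, of liver RNA, of skeletal muscle RNA, of a single library and of fewer mural cells were chosen only after the result was seen, and 2 of them were restated later: that of liver RNA leaves out rbp4, after this gene, abundant in the unlesioned cells, turned out to decide it, and that of skeletal muscle RNA now also asks for the most abundant markers, after 4 of the 5 were seen to be lower in libraries 3 and 4.

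Immediate early and heat shock genes were lower in the lesioned group, with a median log2 fold change of -0.76 over 54 members. The tables argue against a difference confined to libraries 1 and 2 or to libraries 3 and 4, since the median nearer 0 of the 2 parts was -0.58, with camera adjusted p of 5.1e-10 in libraries 1 and 2 and 0.00122 in libraries 3 and 4 (adjusted p = 0.305 with an estimated correlation over all libraries). The test planned for scaling of the libraries could not decide, because size factors move all genes alike, and the list median minus the median of all genes was -0.72 both with TMM and with library size alone. Different handling of the lesioned larvae before or during dissociation stays open, because the count of 50 lower members only restates the pattern, and the labels do not say whether both groups were dissociated at the same time. Handling and the lesion, which is the biological explanation the design gives and was not tested apart from it, cannot be told apart.

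The genes c4b, efemp2a and adamtsl7 were higher in the lesioned group by log2 fold changes of 9.92, 3.48 and 3.64. Liver RNA as the source of c4b is argued against, since 23 liver genes other than rbp4 changed together by -4.68 CPM, with none above 2.35 CPM in the lesioned group (apoa1b 2.14 CPM, fabp10a 0 CPM), while c4b rose by 192 CPM. The lowest log2 fold of the 3 genes in either part was 3.22, so their difference was not confined to 1 part of the samples. The genes were picked from all 8 libraries, with groups that do not overlap, which favours this outcome. It is therefore no independent support. RNA of another cell type among the 10 marker lists stays open although the sort selects GFP: the highest median of the 5 most abundant members of a list was 0.64 (pigment cells), under the bound of 2.94 set beforehand, but in 6 of the 10 lists such a member had over 192 CPM without a lesion (aqp3a 1144 CPM), which would hide a small added share, and the macrophage gene apoeb did not follow c4b within the lesioned group (82.3 CPM with 276 CPM of c4b in lesioned 3, 950 CPM with 24.8 CPM of c4b in lesioned 4), its log2 fold change ranging from 0.41 to 3.17 with 1 library left out. A response of the sorted cells to the lesion stays open as well, as a hypothesis found on the same libraries.

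Actin and contractile genes were lower in the lesioned group with a median of -0.48. Less skeletal muscle RNA stays open, although the sort selects GFP. In libraries 3 and 4, where the contractile list was lower (camera adjusted p = 0.0155), the muscle list was higher with a median of 2.33. But 4 of its 5 most abundant members, tpm2 of the contractile list among them, were lower there (median of the 5 -1.24). In libraries 1 and 2 the contractile and muscle lists both had negative medians (-0.26 and -1.0). The list kept its call with each library left out in turn, which argues against a call made by a single library. But the highest camera adjusted p was then 0.0437, near the limit of 0.05, and only at the preset correlation. With an estimated correlation it was 0.683 over all libraries. Unlesioned 4 stood high for acta2 (14647 CPM, against 9216, 7754 and 4495 CPM in unlesioned 1 to 3). How much of the size of the difference it carried stays open. Fewer mural cells among the sorted cells stay open, since 29 mural markers in no other list had a median of -0.39 with an interquartile range from -0.99 to -0.13. That median is near the one of the contractile list, so fewer mural cells and lower expression per cell after the lesion cannot be told apart.

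Of 212 groups of 4 libraries scanned, 25 held a library far from the other 3. The cutoff gives about 1 in 20, or 10.6, for independent and normally distributed values. CPM and shares need not be so distributed, least of all near the floor, and many of the genes were named by their p. The 2 numbers are therefore no test against chance. In unlesioned 4, macrophage markers took 0.0559% of counts (others up to 0.0136%) and neutrophil markers 0.0212% (others up to 0.00949%). In the same library apoeb had 330 CPM (others up to 59.0), npsn 25.5 CPM (others up to 1.83), c1qb 0.564 CPM (others 0), aspn 45.1 CPM (others from 94.4), ctsk 232 CPM (others from 297) and s100v2 186 CPM (others from 241). In unlesioned 3, timp2b had 465 CPM (others up to 99.5), hspa5 6199 CPM (others up to 2507), hspa8 11943 CPM (others up to 8933), sec13 23.8 CPM (others from 42.6) and dusp2 155 CPM (others from 413). Unlesioned 2 stood apart for fabp7a with 54.8 CPM (others up to 5.49) and mdka with 1526 CPM (others up to 1396), and unlesioned 1 for sncb with 0.729 CPM (others from 2.15).

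Among lesioned libraries, lesioned 4 had 24.8 CPM of c4b (others from 233), 47.2 CPM of fras1 (others up to 30.2) and 3148 CPM of aqp3a (others up to 800). Lesioned 3 had 1109 CPM of myh11a (others up to 910) and 524 CPM of ptgs2a (others up to 277). Lesioned 2 had a sclerotome, tenocyte and myoseptal marker share of 0.448% (others up to 0.354%). Lesioned 1 had 371 CPM of actc1a (others up to 148), 3.28 CPM of fabp7a (others up to 0.821) and 0.128 CPM of sncb (others 0).

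The table also has 92 entries for synthetic spike-in RNAs, on which the study's labels say nothing. They held 158 counts in unlesioned 3, 87 in unlesioned 4, 86 in lesioned 3 and 64 in lesioned 4, above the limit of 3 counts, against 2, 0, 3 and 2 in unlesioned 1, unlesioned 2, lesioned 1 and lesioned 2. The mitochondrial share differed along the same division of the samples (9.41% and 15.4%, exact permutation p = 0.0286, the smallest the test can give). The division was found partly from this share, so that p only restates the choice.

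Each of the 35 splits of the 8 libraries into 4 and 4 was tested in the same way as the real one. For the 3 genes called in edgeR, 2 splits gave as many, so chance cannot be excluded by the limit set beforehand. The other was the split of libraries 1 and 2 from libraries 3 and 4, with 179 genes, which points to a structure of the samples. That split is therefore no plain chance regrouping. Leaving it out, the highest count outside the real split was 0 genes. For the 1821 genes with an unadjusted p under 0.05 the real split was the 1 with as many. The split of libraries 1 and 2 from libraries 3 and 4 gave 1707. This share under 0.05 holds if all 8 libraries are exchangeable and leaves the pairing by number out. For the 678 genes called by DESeq2, 2 splits gave as many, the other being that of libraries 1 and 2 from libraries 3 and 4 with 1006. By the same limit chance cannot be excluded, while the highest count in the remaining splits was 337 genes. For the 8 lists called by camera, 8 splits gave as many, with up to 13, so chance cannot be excluded. List by list, a camera p as low as the real one came in 1 of the 35 splits for erythroid markers, 2 for immediate early and heat shock genes, 2 for glia, 3 for contractile genes, 4 for the endoplasmic reticulum list, 8 for mural markers, 11 for sclerotome, tenocyte and myoseptal markers and 19 for the cell cycle, the real split included. Among the 8 splits that part all 4 pairs of equal number, the highest other values were 0 genes in edgeR, 639 genes with an unadjusted p under 0.05, 50 genes in DESeq2 and 6 lists, and 8 splits are too few for a share under 0.05.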

How the results depend on the processing

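The batch term and the fits of libraries 1 and 2 alone and of libraries 3 and 4 alone were chosen only after the result was seen; the other alternatives were planned.

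The main counts were 3 genes higher, 0 lower and 8 lists called. DESeq2 gave 406 higher and 272 lower, and sample quality weights in limma voom 32 and 31. With no filter on low counts 5 were higher and 1 lower. The batch term gave 7 and 7, libraries 1 and 2 alone 5 and 1, and libraries 3 and 4 alone 0 and 0 (868 genes at an unadjusted p under 0.05). Leaving out 1 library gave 3 to 7 higher and 0 to 1 lower, and 3 to 8 lists. The highest counts, 7 and 1, came without unlesioned 3, and 3 lists were called without unlesioned 2, unlesioned 3 or lesioned 4. All 3 main calls held in each of the 8 leave-one-out fits. With no filter on low counts 6 lists were called, and the glia and erythroid lists were not. The stricter filter left too few erythroid markers to test and called 8 of 26 lists, with the TGF-beta, BMP and PDGF list among them. Camera with an estimated correlation called 0 lists, fry 1, and camera in libraries 1 and 2 alone 4. In libraries 1 and 2 alone the skeletal muscle list was lower (camera adjusted p = 0.000608), opposite to its direction in all libraries. The cause of these differences was not tested. An estimated correlation widens camera's variance, and DESeq2 made more false calls in simulated data (38.9% against 5.88% in edgeR). Those data were drawn with edgeR's own dispersions, so they cannot decide which of the 2 counts is nearer the truth. Fewer libraries enter the fits of a part, but this cannot account for the counts of both parts. In edgeR, libraries 1 and 2 alone gave 2443 genes at an unadjusted p under 0.05, more than the 1821 of all libraries.

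The replicate block gave 2 genes higher and 0 lower and 9 lists; adamtsl7 lost its call and the inflammatory signalling list gained one, and the block changed no other call among the counts and the named genes. RLE and upper-quartile factors, the stricter filter and glmTreat called the same 3 genes, and library size alone those 3 and 1 more. Limma voom called 3, of which 2 were shared. No composition measure passed the exact permutation test, with or without mitochondrial genes, where the lowest adjusted p was 0.243 and 0.183. With 1 library left out only the differences were compared, without a test. Of the 89 named genes, DESeq2 called 40 of the 87 it gave a value for and sample quality weights 13, and no called gene changed sign in any setting. With 19552807 counts or more per library, the spread between libraries (a coefficient of variation of 74.9%) limited the calls more than depth, except for genes near the floor such as c1qb and sncb.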

Other observations

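The sets of genes described here were chosen only after the ranking of genes was seen, while what each set test would show was written before it was run. Both tests gave what was written, but the choice from the same ranking favours that outcome, so the low p-values cannot count for the sets. No test of the parts of the samples was planned for them.

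Genes for cytosolic aminoacyl-tRNA synthetases, the enzymes that load amino acids onto transfer RNAs, were higher in the lesioned cells. All 18 tested members had a positive log2 fold change, with a median of 0.96, and for 11 of them the groups did not overlap, where 9.23% of all tested genes and, by chance, 2.86% have such groups. Camera gave p = 1.8e-11, and with an estimated correlation p = 0.00952. None passed singly over all genes in edgeR, and yars1 had 41.4 ± 4.3 CPM in the unlesioned and 120 ± 26.5 CPM in the lesioned group. The median was 0.85 in libraries 1 and 2 and 1.11 in libraries 3 and 4. The real split was the 1 of 35 with so low a p, an outcome favoured by the choice of the set from that same split. A hypothesis is that the sorted cells may raise their capacity for protein synthesis 1 day after the lesion, and the set was picked because its members stood high in the same data, so these p-values are not independent of the choice.

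Genes for mitochondrial ribosomal proteins, encoded in the nucleus, were higher as well. Of 75 tested members 73 had a positive log2 fold change, with a median of 0.82, and for 42 the groups did not overlap, against the same 9.23% of all tested genes. Camera gave p = 3.7e-22, and with an estimated correlation p = 0.0398, and these p-values too depend on the choice of the set from the same ranking. None passed singly over all genes in edgeR, and mrpl11 had 26.5 ± 2.24 and 59.0 ± 5.25 CPM. The median was 0.63 in libraries 1 and 2 and 1.05 in libraries 3 and 4. The number of genes detected was also higher in the lesioned libraries (19674 and 20975), and a difference in RNA content per cell, which could raise genes of growth together, was not tested.

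Named here after their values were seen, txnb, a thioredoxin, had 123 ± 59.6 and 972 ± 411 CPM in the unlesioned and lesioned groups (log2 fold change 2.99, adjusted p = 0.0769 in edgeR), and clu, the secreted chaperone clusterin, had 123 ± 58.1 and 826 ± 361 CPM (2.75, adjusted p = 0.133 in edgeR). The receptor gene cntfr, for ciliary neurotrophic factor, had 497 ± 99.9 and 178 ± 35 CPM (-1.48, adjusted p = 0.112 in edgeR). The groups did not overlap for any of these 3 genes.

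Of the paralogs of the called genes, efemp2b had 10.8 ± 9.08 and 9.46 ± 7.38 CPM (log2 fold change -0.19, adjusted p = 0.974 in edgeR), and adamtsl5 had 34.5 ± 20.1 and 49.5 ± 25 CPM (0.52, adjusted p = 0.790 in edgeR). Both were named after their values were seen.

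Across genes, the log2 fold changes of libraries 1 and 2 correlated with those of libraries 3 and 4 with a Pearson r of 0.241, and in 8 regroupings of the libraries the size of r was at most 0.0518. Genes are not independent replicates, so no p is given.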
